A study of Mus musculus with 298 samples.

How the data were processed

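RNA from whole blood of 20 mice carrying a tetracycline-off (Tet-off) human BCR-ABL transgene was sequenced in 298 libraries, 1 per mouse and week. The labels give peripheral blood mononuclear cells as the tissue but describe RNA extraction from whole blood, ribosomal RNA depletion and an RNA integrity number above 4. Removal of tetracycline switches the transgene on. The control cohort (3 mice, 57 libraries) stayed on tetracycline water at 0.5 g/L. By design the CML cohort (6 mice, 94 libraries) had the transgene on throughout. In its mouse labelled 487 the transgene was not detected in 16 of 19 libraries. The TOTO cohort (4 mice, 48 libraries) had it on to week 6 and off again afterwards. The TKI cohort (7 mice, 99 libraries) had it on throughout and received nilotinib, an inhibitor of the BCR-ABL kinase, at 50 mg/kg from week 6 to week 10. Whether the week 6 blood was drawn before the first dose, or before tetracycline was given again, is not given in the sources used here, and week 6 was taken as the level before either. The labels name 3 sequencing batches: 2021_E with 4 mice, 2022_A with 11 and 2022_B with 5. Batch is constant within a mouse.

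The values are TPM (transcript abundances per gene scaled to a common sum per library), as deposited by the authors. The submitters' processing notes credit alignment to GRCm39 with STAR and quantification with Salmon, without the versions of these tools. The deposited values cover 14605 genes, of which 14604 reach 1 TPM in at least 5 libraries, 11325 are protein coding and 4 carry human gene names. Gene identifiers were matched to the GENCODE M39 annotation of GRCm39 for 14537 genes, and 64 mouse genes had no match. All columns were mapped to a mouse and week (0 not mapped). TPM sums per library ran from 989100 to 999879. Sequencing depth is unknown because TPM keeps no depth, so no counting error could be given.

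Values were taken as log2(TPM + 1), a pseudocount that understates changes of genes near 1 TPM. Genes with a mean TPM of at least 1 were tested (10519 over all libraries). Each mouse gave 1 change between 2 weeks, which is the fit with mouse as a block. Each cohort had its own change term, except in the induction and sex comparisons. The Tet-off cohorts shared a term in both induction comparisons, and the sex comparison had a term for each sex. Changes were tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 (version 1.17.8 of the data.table package), and a gene passed at a Benjamini-Hochberg adjusted p of 0.05. The eBayes step pools the spread of a gene with that of all genes. Its prior degrees of freedom ran from 11.91 (TOTO minus TKI) to 652.6 (after nilotinib), against 15 and 7 residual ones. Where the prior is far larger, a p value rests mostly on the pooled spread, not on that gene's own spread among mice. Errors beside log2 changes are standard errors unless marked SD. The 12 comparisons, their samples and their tests were fixed before the data were examined, as were 28 gene lists for blood cell types and cell programs. With at least 5 measured members, 26 lists were tested with cameraPR at a preset correlation of 0.01, and again with a correlation estimated from the data. The eosinophil list (2 measured) and the dendritic cell list (4 measured) were not tested. List counts are given over all genes tested and adjusted over the list alone. Because the median of all genes moved between weeks, every comparison was also run on values rescaled per library by median-ratio size factors, called rescaled below.

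Genes were named by a rule: in each comparison the 8 largest rises and the 8 largest falls among genes that passed, with mean TPM of at least 5 and the same sign in at least 80% of the mice, passing over unnamed gene models. In addition 2 to 4 members per list with the smallest p were named, and the transgene, Bcr and Abl1 in every comparison. Near-identical gene copies and pseudogenes (Rpl15-ps3, Rps6-ps4, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Iglc1 and Iglc2, the Stfa family) share sequence, so that their separate values are uncertain.

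A disease score projected each library's change from week 0 of its own mouse on the mean change of CML mice at their last week minus that of control mice at week 18. It is 0 at week 0, and 1 unit is that difference between CML and control mice, so that the mean CML end state need not lie at 1. CML and control mice were scored on axes made without them. Induction genes for the reversal counts were called in Tet-off mice outside the cohort examined. Differences between cohorts in single values were tested by two-sided exact permutation of mouse labels or exact sign flips, and correlations over 10 or more mice by 100000 permutations, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

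That libraries with the same mouse number share a mouse was checked on residuals at weeks 0 and 6: the mean correlation was 0.189 within mice (from -0.453 to 0.566) and -0.00974 between mice. The residuals had only cohort means removed. Libraries of the same mouse also share sex and batch, so the check cannot tell a shared mouse from these. The labelled sex was checked in 298 libraries and 0 did not match, which does not test cohort or mouse labels. The fits were tested on simulated data, with 100 genes shifted by 1 and 100 by 2 on the log2 scale, and no shifted gene was called with the wrong sign. Of the 100 genes shifted by 2, 100 were called in the induction change of Tet-off mice, 100 in TKI week 10 against week 6, 95 after nilotinib and 96 in TOTO week 12 against week 6. In the differences between cohorts 91 were called for TKI minus CML, 82 for TOTO minus TKI, 61 for TOTO minus CML, 39 for TKI week 10 against week 0 minus control and 21 between the sexes. The other 3 comparisons with control called few: 2 for Tet-off minus control at week 6, 0 for the CML end state and 1 for TOTO at week 18. At a shift of 1, the same comparisons called 40, 88, 36, 22, 30, 23, 6, 1, 1, 0, 0 and 0 genes in the order given. False calls ranged from 0 to 13. A simulated list of 20 genes shifted by 0.7 had a p from 2.05e-22 to 0.000954, and unshifted lists from 0.122 to 0.986. The simulated noise was drawn independently for each gene, whereas in the real libraries most genes moved together. The simulated calls and list p values therefore hold for independent genes only, and do not measure false calls in the real data.

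Alternatives were another pseudocount (0.1), no filter, rescaling, haemoglobin and erythroid genes left out, no mouse block, a batch term, neighbouring weeks, and each mouse of a small cohort left out in turn. Further ones were chosen after seeing the data: week 1 in place of week 0, the CML mouse labelled 487 left out, and TKI mice 507 and 512 left out. No library was excluded from the comparisons.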

Results

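The libraries followed 20 mice from week 0 to week 18 or to an earlier last week. They were weekly in 3 cohorts, while TOTO mice had libraries at weeks 0 to 8, 12, 16 and 18 only. All 3 control mice and all 4 TOTO mice had a library at week 18. The last weeks of the CML mice were 7 (mouse 477), 11 (484), 16 (542) and 18 (480, 487 and 541), and those of the TKI mice ran from 10 to 16. Haemoglobin transcripts made up a median of 42.6% of TPM per library (range 0.33 to 74.8%). The small cytoplasmic RNA Rn7s2 made up 31.7% (14.5 to 56.0%), and the 10 most abundant genes together 79.2% (49.1 to 93.0%). The median number of genes at 1 TPM or more was 9965 (2552 to 13256). The library of control mouse 490 at week 17 had the lowest median correlation with the other libraries, 0.418, against a median of 0.922 over all libraries.

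The first question was whether the transgene followed the switch. Human BCR-ABL transcripts stood at a mean of 0.0619 TPM at week 0 in CML mice and 0.172 TPM in TKI mice. At week 6 the mean was 13.4 ± 10.8 TPM (SD, n = 7) in TKI mice, 7.20 ± 6.19 (n = 4) in TOTO mice and 3.16 ± 4.08 (n = 6) in CML mice, with 0 in the 3 control mice. In CML mice at week 18 it was 23.7 ± 24.8 TPM (n = 3). After the switch back, TOTO mice stood at 0.0886 ± 0.0657 TPM at week 7 (log2 change -2.60 ± 1.16 SD, lower in 4 of 4, exact sign-flip p = 0.125, the smallest 4 mice allow). At week 8 all 4 TOTO mice stood at 0 TPM. Control libraries were at 0 in 49 of 57 and reached at most 0.716 TPM. The mouse labelled CML 487 was at 0 in 16 of its 19 libraries, with a maximum of 0.409 TPM, inside the range of the control libraries, and it stays in every comparison below that uses CML mice. The other 16 Tet-off mice ran from 0.358 to 36.0 TPM at week 6.

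**Figure D1:**
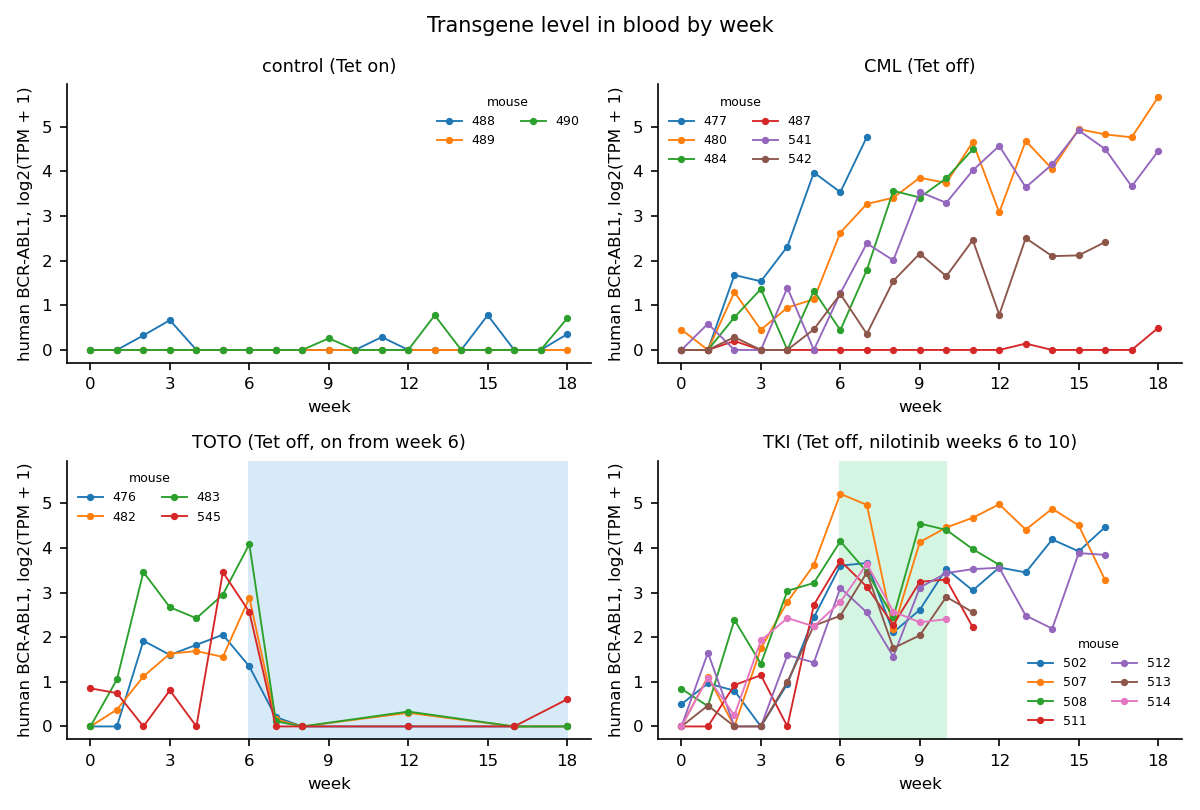
Human BCR-ABL level, as log2(TPM + 1), of each mouse by week, 1 panel per cohort and 1 line per mouse. Before the log2 step the means at week 6 were 13.4 TPM in TKI, 7.20 in TOTO and 3.16 in CML mice and 0 in control mice. The mouse labelled CML 487 stayed at or below 0.409 TPM.

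Under nilotinib the transgene reached its lowest mean at week 8, 3.49 ± 1.07 TPM (SD, n = 7), from 13.4 at week 6. It fell by 1.45 ± 0.88 (SD) on the log2 scale in 7 of 7 mice (exact sign-flip p = 0.0156, the smallest 7 mice allow), or by 0.90 after rescaling. The log2 change from week 6 was -0.026 at week 7 (exact p = 0.969) and -0.433 at week 9 (exact p = 0.0625). By week 10 the transgene was back at 11.6 ± 6.49 TPM, a log2 change of 1.36 from week 8 (exact p = 0.0313) and of -0.09 from week 6 (exact p = 0.594). Week 8 was picked as the lowest week, and the p values in this paragraph are not adjusted over weeks. A rise after a lowest week is partly built in. The rescaled change from week 6 to 8 differed between TKI mice (-0.901 ± 0.667, SD, n = 7) and CML mice (0.988 ± 0.884, n = 5) by -1.889 (exact permutation p = 0.00126). It was -1.16 in the 4 TKI mice of batch 2022_A and -0.558 in the 3 of 2022_B. The CML mice gave 0.896, 2.41 and 0.368 in the 3 batches, the last with the mouse labelled CML 487.

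What 6 weeks of BCR-ABL changes in blood was read from weeks 0 and 6 of 17 Tet-off mice. Human BCR-ABL rose by 2.49 ± 0.26 (adjusted p = 3.04e-10, 16 of 17 mice), whereas mouse Bcr (-0.12, adjusted p = 0.817, rescaled 0.31) and Abl1 (-0.61, adjusted p = 0.17) did not pass. The mouse labelled CML 487 is among the 17. The largest rises were in proteins of neutrophil secondary granules. Ngp, which encodes a neutrophilic granule protein (ENSMUSG00000032484.9, GRCm39 chromosome 9, 110248815 to 110252086), rose by 5.64 ± 0.45 (adjusted p = 9.84e-14, 16 of 17 mice, 4.23 to 291 TPM). Ltf, encoding lactoferrin, rose by 4.80 ± 0.39 in 17 of 17 mice, and Camp, the cathelicidin antimicrobial peptide, by 4.41 ± 0.38. The acute-phase gene Saa3 rose by 4.20 ± 0.35, the iron-siderophore binder Lcn2 by 3.23 ± 0.44 and the collagenase Mmp8 by 2.85 ± 0.42. Of 17 secondary granule genes 15 rose (15 adjusted over the list alone) and 0 fell, with a median of 1.75 (rescaled 2.21). This list also passed with an estimated correlation (adjusted p = 0.000899), but not after rescaling (adjusted p = 0.389 with an estimated correlation).

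Mature neutrophil genes rose in 14 of 21 (18 adjusted over the list alone; median 1.38; adjusted p = 0.18 with an estimated correlation). Basophil and mast cell genes rose in 9 of 15 (11 adjusted over the list alone; adjusted p = 0.0534 with an estimated correlation). Among them were the proteases Mcpt8 (2.59 ± 0.26, 0.314 to 9.0 TPM) and Prss34 (2.17 ± 0.22). B cell genes fell in 17 of 19 (18 adjusted over the list alone; median -1.38, rescaled -0.94; adjusted p = 0.416 with an estimated correlation). Counted from week 1 in place of week 0 the B cell median was 0.07 with 0 of 19 past the threshold (rescaled -0.14, 6 of 19 lower). Fcer2a, the low-affinity IgE receptor of B cells (ENSMUSG00000005540.11, chromosome 8, 3731737 to 3744183), fell by 2.19 ± 0.36 in 17 of 17 mice. The B-lineage transcription factors Bach2 (-2.02) and Pax5 (-1.69) and the lambda light chain genes Iglc1 (-2.02) and Iglv1 (-1.92) fell as well.

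T cell genes fell in 11 of 20 (14 adjusted over the list alone; adjusted p = 0.586 with an estimated correlation), including the homing receptor Ccr7 (-1.54). NK cell genes fell in 9 of 16 (13 adjusted over the list alone; adjusted p = 0.556 with an estimated correlation), including the receptors Klra9 (-1.30) and Klra8 (-1.27). MHC class II genes fell in 6 of 11 (10 adjusted over the list alone; adjusted p = 0.556 with an estimated correlation), but from week 1 the list median was 0.40 and 3 of 11 rose. Platelet and megakaryocyte genes rose in 14 of 20 (16 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation), with Gp1bb, a subunit of the von Willebrand factor receptor, at 2.27 ± 0.35 and P-selectin (Selp) at 1.82 ± 0.34. That direction flipped from week 1, where the platelet median was -0.42 and 4 genes fell (19 rescaled). Of 59 ribosomal protein genes 0 passed as deposited, while 41 rose after rescaling, and the list median flipped from -0.15 to 0.31. Glycolysis genes rose in 6 of 19 (10 adjusted over the list alone; adjusted p = 0.546 with an estimated correlation), with the kinases Hk3 (1.13) and Pkm (1.05, rescaled -0.22 from week 1). Mitochondrially encoded genes fell in 7 of 13 (12 adjusted over the list alone; adjusted p = 0.564 with an estimated correlation). From week 1 the list median was -0.12 with 0 of 13 past the threshold by limma (0 over the list alone). Their share of TPM moved from 0.574% at week 0 to 0.230% at week 1 and 0.228% at week 6 in CML mice, but from 0.242 to 0.324 and 0.323% in TKI mice.

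In the induction change in Tet-off mice 2153 genes passed, 463 higher and 1690 lower (21.5% higher). The pooled direction joins cohorts that differed, counting called genes with the sign of the difference from control. Without the TKI mice 209 such genes rose and 7274 fell, but without the TOTO mice 507 rose and 112 fell. The median of all genes in the mean change was -0.339, with a spread of 1.23 (SD) over mice and values below 0 in 7 of 17, and after rescaling, where it was 0.063, 7701 passed with 55.1% higher, 2131 of them shared. From week 1 the count was 2204 with 87.7% higher and 384 shared, so that the direction of the bulk of genes depended on the week 0 libraries, while the secondary granule list rose either way (16 of 17, adjusted p = 0.00361 with an estimated correlation). The secondary granule median minus the all-gene median was 1.17 in 2021_E (2 mice), 2.64 in 2022_A (10 mice) and 1.78 in 2022_B (5 mice). The all-gene median itself was -0.627, -0.515 and 0.126. Without TOTO mouse 483 the count was 1293, and with a batch term it was 736.

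Subtracting the change of the 3 control mice over the same weeks was meant to take out age and bleeding. That these act alike in both groups was not tested. The human transgene differed by 2.49 ± 0.67 (adjusted p = 0.416, rescaled 2.62 with adjusted p = 0.0291), Bcr by 0.61 (adjusted p = 1) and Abl1 by 0.32 (adjusted p = 1). Only Ngp (5.93 ± 1.16, adjusted p = 0.0241) and Saa3 (4.62 ± 0.90, adjusted p = 0.0241) passed, both higher, and with Camp (4.60 ± 0.98, adjusted p = 0.0662) they were the furthest from control. Both calls were lost when any of control mice 488, 489 or 490 was left out, with adjusted p of 0.33 or more. The secondary granule list had a median of 2.64, with 1 of 17 genes higher over all genes, 15 adjusted over the list alone, and passed with an estimated correlation (adjusted p = 0.00166), but not after rescaling (0.477). Of mature neutrophil genes 0 passed (7 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). B cell genes had a median of -0.29 with 0 of 19 passing, and 11 lower after rescaling (-0.81). The median of all genes was 0.402. After rescaling 1900 genes passed, 60.2% higher. At unadjusted p under 0.05 limma gave 264 genes. For this difference the secondary granule median minus the all-gene median was 0.654 in 2021_E (2 against 2 mice) and 3.51 in 2022_A (10 against 1). The all-gene median itself was 0.376 and -0.215, and 2022_B held no control mouse.

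The end state of the disease was taken from the last library of each of 6 CML mice against week 0, minus control at week 18. The transgene stood higher by 3.29 ± 0.61 (adjusted p = 0.000445, 6 of 6 mice, 0.0619 to 20.5 TPM), with Bcr (-0.00, adjusted p = 1) and Abl1 (-0.07, adjusted p = 1) not past the threshold. The mouse labelled CML 487 is 1 of the 6. Of 19 genes that passed, all higher, 6 were on the secondary granule list, 2 on the basophil and mast cell list and 3 were human. Ngp was higher by 7.04 ± 0.83 (adjusted p = 6.78e-10, 3.77 to 758 TPM in CML mice), Camp by 6.08 ± 0.70, Ltf by 5.24 ± 0.87 and Lcn2 by 4.14 ± 0.95. Itgb2l, an integrin chain of the neutrophil lineage, was higher by 4.04 ± 0.62, the chitinase-like Chil3 by 3.91 ± 0.92 and the protease inhibitor Stfa2 by 3.65 ± 0.65. Mcpt8 was higher by 3.64 ± 0.67 and Prss34 by 3.09 ± 0.61. Each of these was higher in 6 of 6 mice. The count for the CML last sample change minus control was 5 with pseudocount 0.1, 4 with no replicate block, 9 from week 1 and 80 with a batch term. The transgene, Lcn2, Chil3, Mcpt8 and Prss34 lost their calls in the first 3 of these (transgene adjusted p = 0.214, 0.298 and 0.0771), and Stfa2 in the first 2.

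Secondary granule genes were higher in 6 of 17 (15 adjusted over the list alone; median 2.79) and passed with an estimated correlation (adjusted p = 1.03e-07, rescaled 2.08e-08). Mature neutrophil genes passed as a list (median 1.89, 0 of 21 genes, 8 adjusted over the list alone, adjusted p = 0.0391 with an estimated correlation, 0.211 rescaled). Basophil and mast cell genes were higher in 2 of 15 (7 adjusted over the list alone; adjusted p = 0.00131 with an estimated correlation, 0.253 rescaled). B cell genes were lower as a list (median -1.72, 0 of 19 genes, 0 adjusted over the list alone, adjusted p = 0.0399 with an estimated correlation, 0.0813 rescaled). Fcer2a stood at -2.61 ± 0.90 (adjusted p = 0.658, rescaled -2.94 with 0.0069), and the complement receptor Cr2 at -2.28 (adjusted p = 1, rescaled -2.72 with 0.00869). After rescaling 957 genes passed, 49.4% higher, and 18 of the 19 were among them. The STAT5 target Cish was at 1.67 (adjusted p = 0.448, rescaled 1.82 with 0.0293). Without CML 487, 56 genes passed. Without TOTO mouse 482, 483 or 545, whose spread enters the fit, the counts were 36, 33 and 43. Lcn2 and Chil3 lost their calls without control mouse 489 (adjusted p = 1.0 for both) or 488 (0.124 and 0.157). For this difference the secondary granule median minus the all-gene median was 2.86 in 2021_E (2 against 2) and 3.50 in 2022_A (2 against 1). The all-gene medians themselves were 0.986 and -0.249 (0.079 over all mice).

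**Figure D2:**
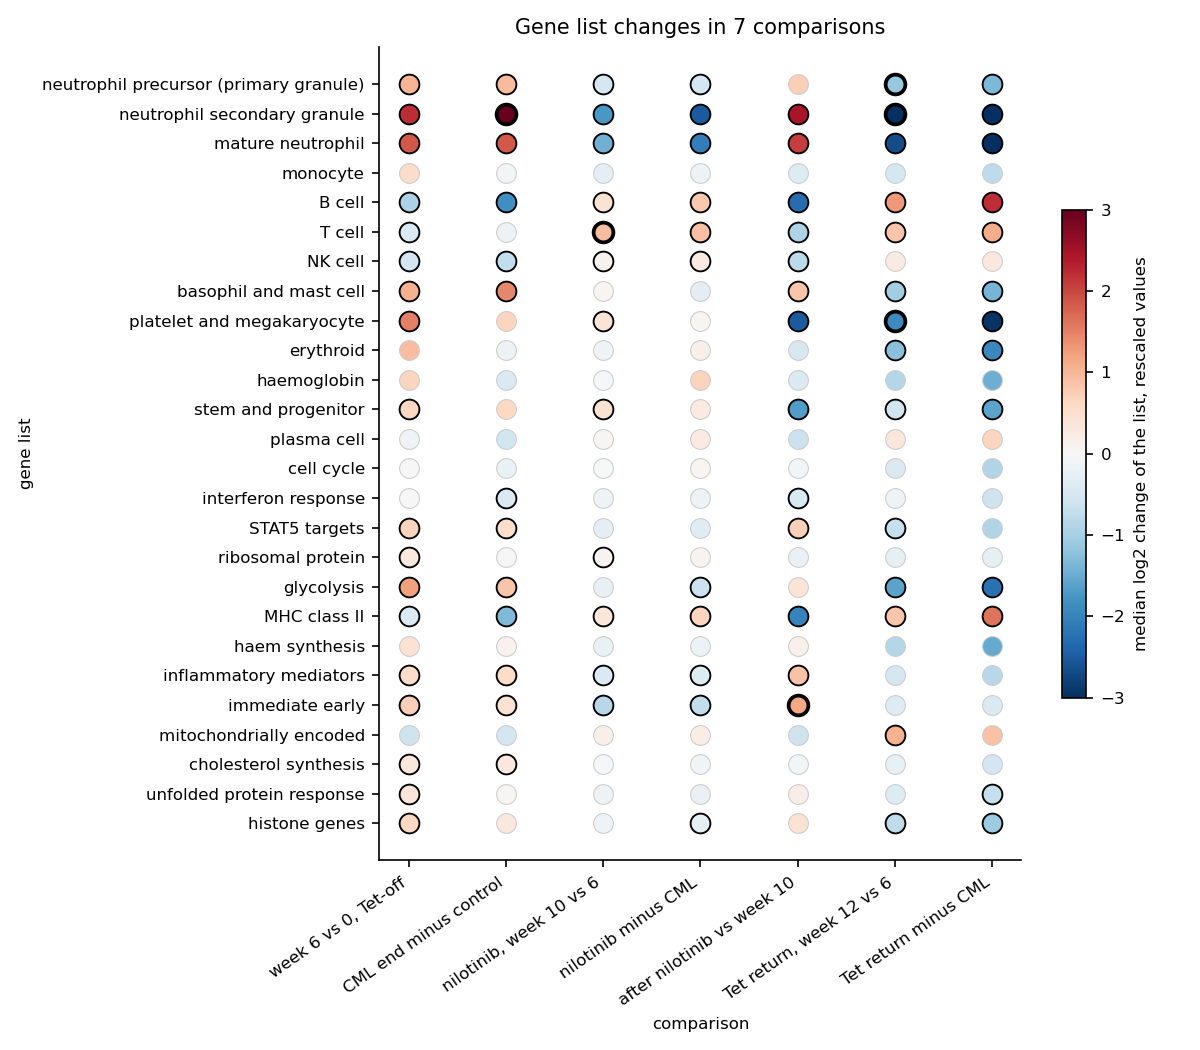
Median rescaled log2 change of 26 gene lists (vertical) in 7 comparisons (horizontal) as colour, with the scale ending at 3 and -3, a black outline where the list passed with the preset correlation and a thick outline where it passed with an estimated one. Secondary granule genes were at 2.21 in the induction change, -1.74 in TKI week 10 against week 6 and -3.31 in TOTO week 12 against week 6, and ribosomal protein, interferon and several other medians flip sign without rescaling.

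The effect of 4 weeks of nilotinib was measured from week 6 to week 10 in 7 TKI mice. The transgene (-0.09 ± 0.26, adjusted p = 0.902), Bcr (0.48, adjusted p = 0.14, rescaled 0.42 with 0.0246) and Abl1 (0.13, adjusted p = 0.789) did not pass. Neutrophil genes fell. The secreted protein gene Crispld2 fell by 2.41 ± 0.37 (adjusted p = 0.000892, 7 of 7 mice, 26.0 to 4.95 TPM) and Ngp by 2.12 ± 0.38 (6 of 7 mice, 446 to 109 TPM). Lcn2 (-2.09), the neutrophil surface proteins Cd177 (-2.06) and Ly6g (-2.02), and Mmp9 (-1.78), a gelatinase, fell as well. Of 17 secondary granule genes 15 fell and 0 rose (median -1.69; adjusted p = 0.0514 with an estimated correlation). Of 21 mature neutrophil genes 18 fell (median -1.41; adjusted p = 0.129 with an estimated correlation). T cell genes rose in 19 of 20 (median 0.99; adjusted p = 0.129 with an estimated correlation, 0.0422 rescaled), among them the T cell receptor constant chain Trac (1.07), Cd8a (1.12), Cd28 (1.14 ± 0.19) and the interleukin 7 receptor Il7r (1.17). Of 19 B cell genes 2 rose, 4 adjusted over the list alone and 11 after rescaling, with Fcer2a at 1.19 ± 0.24 (6 of 7 mice). Immediate early genes fell in 8 of 16 (10 adjusted over the list alone; adjusted p = 0.255 with an estimated correlation), with Egr1 at -1.51 and Ier3 at -1.63. Inflammatory genes fell in 6 of 15, with the interleukin 1 receptor antagonist Il1rn at -1.84 and Nlrp3 at -1.09 (adjusted p = 0.629 with an estimated correlation).

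For TKI week 10 against week 6, 839 genes passed, 328 higher and 511 lower, with an all-gene median of 0.068. After rescaling 3640 passed, 833 of them shared, and 45.1% against 39.1% were higher. Without haemoglobin and erythroid genes 2387 passed with 58.9% higher, and with week 9 in place of week 10 the count was 354 with 54.8% higher, so that the direction of most calls was not settled. The secondary granule median minus the all-gene median was -2.26 in the 4 mice of batch 2022_A and -1.03 in the 3 of 2022_B. Within the treatment the neutrophil fall came early. From week 6 to week 8 the rescaled secondary granule mean fell by 1.54 ± 0.58 (SD) and the mature neutrophil mean by 1.46 ± 0.56, while B cell (0.50 ± 0.31), T cell (0.49 ± 0.21) and platelet genes (0.84 ± 0.26) rose, each in 7 of 7 mice (exact sign-flip p = 0.0156, adjusted over 26 lists 0.0451). From week 8 to week 10 the secondary granule mean moved by 0.00624 (exact p = 0.938). The rescaled transgene rose by 0.80 in 7 of 7 mice (exact p = 0.0156) from week 8, its lowest week.

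**Figure D3:**
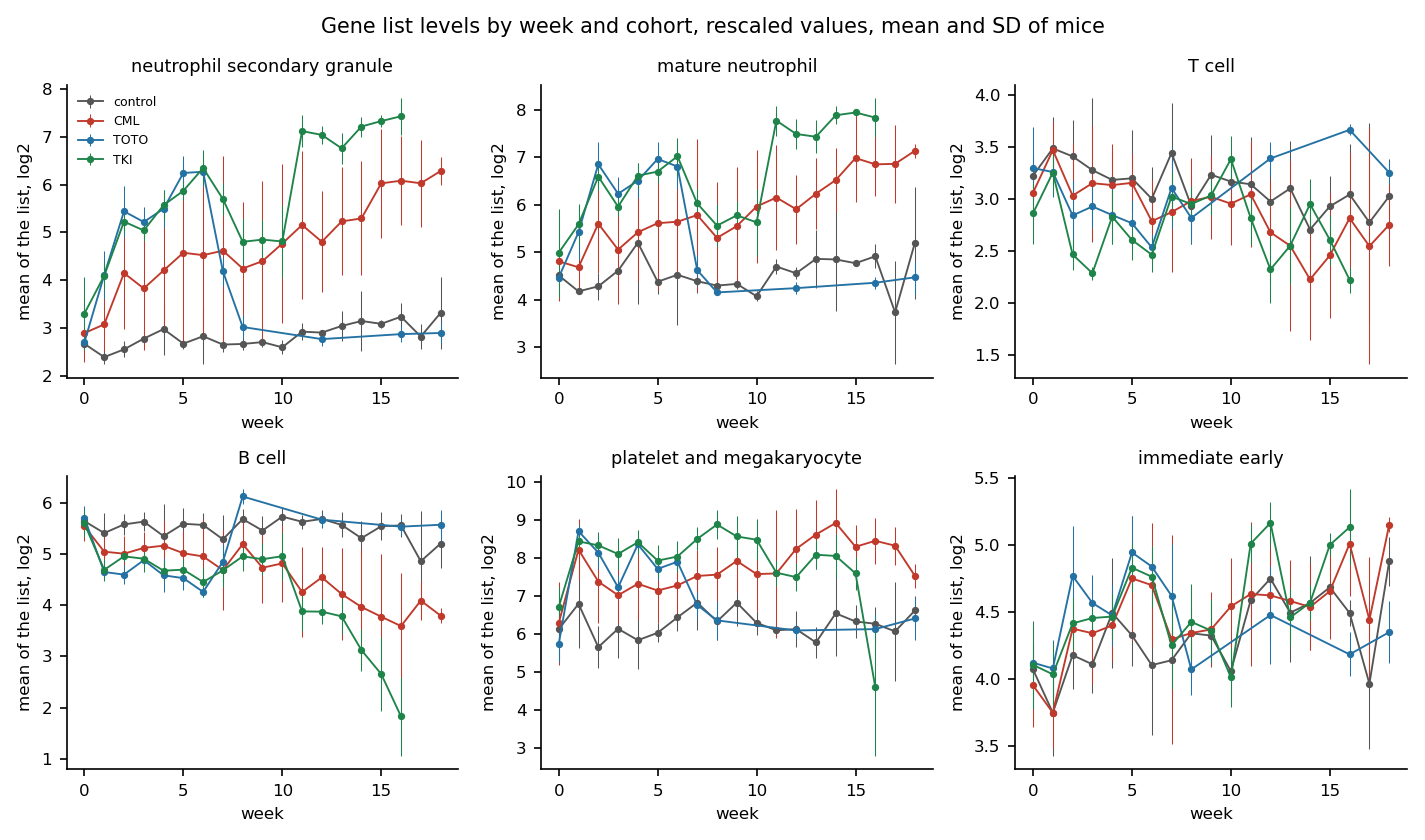
Rescaled level (log2) of 6 gene lists by week, 1 line per cohort, with points as means over mice and bars as SD, for weeks with at least 3 mice. From week 6 to week 8 the secondary granule list moved by -1.54 in TKI and by -3.25 in TOTO mice, and from week 10 to week 11 by 2.21 in TKI mice.

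Untreated CML mice over the same weeks served as the comparison for nilotinib (7 TKI against 5 CML mice, the mouse labelled CML 487 among them). The transgene change was lower in TKI mice, at -1.48 ± 0.40 (adjusted p = 0.0362, rescaled -1.46). This call was lost without CML mouse 541 (adjusted p = 0.139) or 484 (0.149). Bcr differed by -0.05 (adjusted p = 0.973) and Abl1 by 0.10 (adjusted p = 0.948). Ngp was lower, at -3.83 ± 0.58 (adjusted p = 0.00187), as were Camp (-3.28), Lcn2 (-3.27), Ltf (-3.19) and S100a9, a calcium-binding alarmin of neutrophils, at -3.14 (6976 to 1793 TPM in TKI mice). Without CML mouse 484 the adjusted p of Lcn2 was 0.0573. Secondary granule genes were lower in 15 of 17 (median -2.73) and passed with an estimated correlation (adjusted p = 0.0148), though not after rescaling (0.258). Mature neutrophil genes were lower in 18 of 21 (20 adjusted over the list alone; adjusted p = 0.0538 with an estimated correlation). Fcer2a was higher by 1.58 ± 0.37 (adjusted p = 0.0138). T cell genes did not pass singly as deposited (0 of 20, 4 adjusted over the list alone), and 18 were higher after rescaling. The helper T cell receptor Cd4 stood at 1.01 (adjusted p = 0.054, rescaled 1.09 with 0.00511). For TKI week 10 against week 6 minus CML, 375 genes passed, 3 higher and 372 lower (2169 rescaled, 39.7% higher, 371 shared), with an all-gene median of -0.12. Without haemoglobin and erythroid genes 1054 passed with 56.3% higher, with week 9 in place of week 10 only 36, and with a batch term 842. Besides Fcer2a, the higher ones were the gene models Gm56158 and Gm50020, named after their values were seen. The count was 113 without CML mouse 484 and 154 without 541. For this difference the secondary granule median minus the all-gene median was -3.94 in 2022_A (4 against 1) and -1.42 in 2022_B (3 against 2). The all-gene medians themselves were -0.877 and 0.12.

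What changed after nilotinib stopped was read from week 10 to the last library of 6 TKI mice. The transgene (-0.34, adjusted p = 0.434) and Abl1 (-0.13, adjusted p = 0.805) did not pass. Mouse Bcr (ENSMUSG00000009681.11, chromosome 10, 74896400 to 75020753) fell by 1.49 ± 0.31 (adjusted p = 2.43e-05, 6 of 6 mice, 17.6 to 5.90 TPM), and the adjusted p of Bcr in TKI last sample against week 10 was 0.0763 without TKI mice 507 and 512. Neutrophil genes rose above their level under treatment. Stfa2 rose by 5.15 ± 0.31 (adjusted p = 5.11e-48, rescaled 0.000674, 1.51 to 195 TPM), the resistin-like Retnla by 5.06 ± 0.30, Chil3 by 3.93 ± 0.36 (148 to 2168 TPM) and the interleukin 1 decoy receptor Il1r2 by 3.38, each in 6 of 6 mice. As deposited this fit had 652.6 prior against 7 residual degrees of freedom. Its p values and standard errors therefore rest mostly on the spread pooled over genes, and overstate what 6 mice can settle. Of 17 secondary granule genes 15 rose (median 2.41; adjusted p = 0.00711 with an estimated correlation, 0.21 rescaled). Of 21 mature neutrophil genes 19 rose (adjusted p = 0.0627 with an estimated correlation).

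Lymphocyte and platelet genes moved the other way. B cell genes fell in 18 of 19 (median -2.40; adjusted p = 0.0627 with an estimated correlation), with Fcer2a at -3.65 ± 0.32 (29.8 to 1.5 TPM) and Cr2 at -2.85. T cell genes fell in 16 of 20 (17 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation), with Cd28 at -1.57, and NK cell genes in 13 of 16 (adjusted p = 0.494 with an estimated correlation), with Ncr1 at -1.67. MHC class II genes fell in 11 of 11 (median -2.08; adjusted p = 0.163 with an estimated correlation), with the transactivator Ciita at -2.21. Platelet genes fell in 20 of 20 (median -2.61; adjusted p = 0.0627 with an estimated correlation), and the serotonin transporter Slc6a4 fell by 3.86 ± 0.36 (249 to 51.4 TPM). Immediate early genes rose in 12 of 16 (13 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation, 0.0332 rescaled), with Ier3 at 2.27 and the phosphatase Dusp1 at 1.77. Of 32 interferon genes 11 fell (adjusted p = 0.703 with an estimated correlation), with the GTPase Igtp at -2.41. For the TKI last sample against week 10, 2964 genes passed (1196 higher, 1768 lower, 40.4% higher), and 5550 after rescaling (2834 shared, 50.0% higher). The all-gene median was -0.061. Without TKI mice 507 and 512, whose week 16 libraries lay apart from the others, 1244 passed. With a batch term 2545 passed, and 62.9% of them were higher in place of 40.4%. The secondary granule median minus the all-gene median was 3.01 in the 4 mice of batch 2022_A and 1.59 in the 2 of 2022_B. The all-gene medians themselves were -0.27 and 0.363.

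The first step after treatment was from week 10 to week 11. In 6 TKI mice the rescaled secondary granule mean moved by 2.21 ± 0.57 (SD) and the mature neutrophil mean by 2.04 ± 0.57, against -0.98 ± 0.35 for B cell and -1.01 for platelet genes, each in 6 of 6 mice (exact sign-flip p = 0.0313, the smallest 6 mice allow; adjusted 0.0542). In 5 CML mice over the same week the secondary granule mean moved by 0.39 (exact p = 0.125), the mature neutrophil mean by 0.19 (exact p = 0.25) and the platelet mean by 0.016 (exact p = 1.0). B cell genes of the CML mice moved down as well, by -0.56 in 5 of 5 (exact p = 0.0625, the smallest 5 mice allow), and the cohorts' steps were not tested against each other. Haemoglobin transcripts made up 28.3% of TPM at week 10 and 7.24 ± 9.51% (SD, n = 6, range 0.33 to 24.6) at week 11 in TKI mice. They stood at 27.0% at week 12 and 33.6% at week 16.

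**Figure D4:**
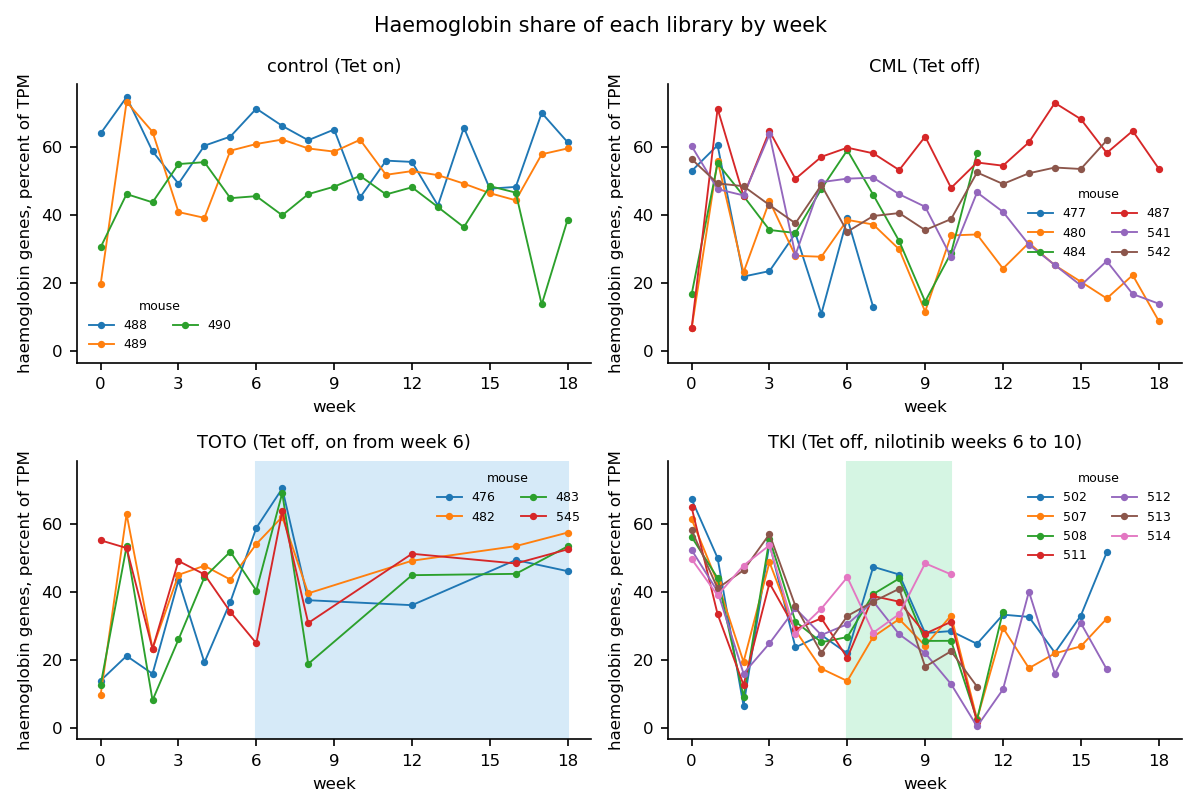
Share of TPM taken by haemoglobin transcripts (percent) in each mouse by week, 1 panel per cohort and 1 line per mouse. In TKI mice the mean was 58.5% at week 0, 27.2% at week 6 and 7.24% at week 11, and in control mice 38.1% at week 0 and 59.3% at week 6.

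Switching BCR-ABL off again was followed in 4 TOTO mice from week 6 to week 12. The transgene fell by 2.56 ± 0.35 (adjusted p = 1.7e-07, 4 of 4 mice, 7.20 to 0.124 TPM). Bcr was at 0.25 (adjusted p = 0.576), which flipped to -0.58 after rescaling (adjusted p = 0.00116). Abl1 (ENSMUSG00000026842.17, chromosome 2, 31578333 to 31697112) rose by 1.02 (adjusted p = 0.0127), but not after rescaling (0.23, adjusted p = 0.1) and not without TOTO mouse 476 (Abl1 in TOTO week 12 against week 6 at 0.61, adjusted p = 0.19). Ngp fell by 7.15 ± 0.43 (adjusted p = 2.17e-21, rescaled -7.73, 302 to 0.71 TPM), Camp by 5.52 ± 0.38, Saa3 by 4.91, Chil3 by 4.61 and Lcn2 by 4.53, each in 4 of 4 mice. Retnlg, a resistin-like gene of mature neutrophils, fell by 3.71 (1147 to 66.3 TPM). Secondary granule genes fell in 15 of 17 (median -2.39, rescaled -3.31) and passed with an estimated correlation on both scales (adjusted p = 7.03e-05, rescaled 0.0346). Mature neutrophil genes fell in 19 of 21 (median -1.79; adjusted p = 0.0357 with an estimated correlation, 0.259 rescaled).

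B cell genes rose in 19 of 19 (median 2.26, rescaled 1.31; adjusted p = 0.309 with an estimated correlation), with Fcer2a at 3.13 ± 0.40 (7.70 to 75.6 TPM), Bach2 at 2.74 and the early B cell factor Ebf1 at 2.35. T cell genes rose in 19 of 20 (median 1.62; adjusted p = 0.377 with an estimated correlation), with Ccr7 at 2.54 and Cd5 at 1.71. MHC class II genes rose in 11 of 11 (median 1.802; adjusted p = 0.377 with an estimated correlation), with H2-Ob at 2.35. NK cell genes rose in 14 of 16 as deposited and in 5 after rescaling. Mitochondrially encoded genes rose in 12 of 13 (adjusted p = 0.377 with an estimated correlation) and in 7 after rescaling. Platelet genes fell in 10 of 20 (adjusted p = 0.271 with an estimated correlation) and in 20 of 20 after rescaling (median -1.92, adjusted p = 0.0399 with an estimated correlation), with Gp1bb at -2.39 and Selp at -2.22. Glycolysis genes fell in 2 and rose in 1 of 19 as deposited, and fell in 17 after rescaling (adjusted p = 0.232 with an estimated correlation), with Hk3 at -1.67. The medians of 13 further lists, among them ribosomal protein (0.69), interferon (0.64) and monocyte genes (0.43), were above 0 as deposited and below 0 after rescaling.

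For TOTO week 12 against week 6, 5268 genes passed, 91% higher, with an all-gene median of 0.665. After rescaling 6479 passed, 44.7% higher, 3365 of them shared. The count was 2411 without TOTO mouse 476 and 3279 without 483. The rescaled secondary granule mean moved by -2.08 ± 0.33 (SD) from week 6 to 7 and by -3.25 ± 0.22 to week 8, in 4 of 4 mice (exact p = 0.125, the smallest 4 mice allow), while B cell genes moved by 0.59 and 1.86 ± 0.17. The week 7 libraries of TOTO mice held 66.3% haemoglobin, and that of mouse 545 had 5541 genes at 1 TPM or more and a median correlation of 0.831 with other libraries, so the week 7 values are less certain. All TOTO mice were in batch 2022_A, so no other batch could be compared, and with a batch term on the change only 103 genes passed, 32.0% of them higher.

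CML mice kept off tetracycline over weeks 6 to 12 were the comparison (4 mice). The mouse labelled CML 487, at 0 TPM of the transgene in 16 of its 19 libraries, was among them. Against these mice the transgene of TOTO mice was lower, at -3.38 ± 0.50 (adjusted p = 4.4e-07). Bcr was at 0.31 (adjusted p = 0.614, rescaled -1.17) and Abl1 at 1.83 (adjusted p = 0.00158, rescaled 0.48). Ngp was lower, at -9.12 ± 0.61 (rescaled -10.41), as were Camp (-7.34) and Lcn2 (-5.62). Fcer2a was higher by 5.05 ± 0.57 (rescaled 3.50), the IgM receptor Fcmr by 4.49, the immunoglobulin heavy chain Ighm by 4.07 and Cd4 by 2.73. Secondary granule genes were lower in 15 of 17 (median -2.92) and passed with an estimated correlation (adjusted p = 0.00029, rescaled 0.0538). B cell genes were higher in 19 of 19 (median 3.79, rescaled 2.21; adjusted p = 0.207 with an estimated correlation) and MHC class II genes in 11 of 11 (median 3.31; adjusted p = 0.334 with an estimated correlation). Ribosomal protein genes were higher in 43 of 59 as deposited, a direction that flipped after rescaling (1 higher, 10 lower). In total 6219 genes passed, 94.1% higher, with an all-gene median of 1.117, and 6795 after rescaling, 43.7% higher, 35 of them called the opposite way. No CML mouse of the TOTO batch had a week 12 library, so that batch and cohort could be separated only by a batch term, with which 59 genes passed.

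The change from week 0 to week 18, 12 weeks after the switch back, was compared between 4 TOTO and 3 control mice, so that differences at week 0 enter every value. The transgene (-0.41, adjusted p = 1), Bcr (-0.34) and Abl1 (-0.27) did not pass. Only Gm28438 (5.49 ± 1.05, adjusted p = 0.00819, 3 of 4 mice) and the minor spliceosome RNA Rnu4atac (3.53 ± 0.75, adjusted p = 0.0441, 2 of 4 mice) passed, both named after their values were seen. After rescaling 0 genes passed by limma (108 at unadjusted p under 0.05, against 37 as deposited). No list had a member past the threshold. The changes of the haemoglobin (median 0.90) and erythroid lists (0.80) were higher and passed with an estimated correlation (adjusted p = 0.00183 for both, 0.654 rescaled), with Hbb-bs and Hba-a2 at 0.97 each (adjusted p = 1). Haemoglobin made up 22.8% of TPM in TOTO and 38.1% in control mice at week 0, but 52.3 and 53.3% at week 18. From week 1 the medians were 0.51 and -0.084, and neither list passed with an estimated correlation (adjusted p = 0.619 and 0.74). Immediate early (median -0.56) and inflammatory lists (-0.50) were lower after rescaling (adjusted p = 0.00577 and 0.0376 with an estimated correlation), but not as deposited (0.463 for both), with Fos at -1.51 and Dusp1 at -1.52. The all-gene median was -0.304. In simulated data this comparison called 1 of 100 genes shifted by 2. Without control mouse 488, or TOTO mouse 476, 482, 483 or 545, the count was 7, 6, 7, 6 and 7. Batch 2022_A held all 4 TOTO mice and 1 control mouse, with an all-gene median of -0.873 between them.

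The end of nilotinib was compared with control as the change from week 0 to week 10 in 7 TKI mice minus 3 control mice. The transgene was higher by 3.30 ± 0.51 (adjusted p = 7.03e-06, rescaled 3.13 with 0.0362). Bcr was higher by 1.96 (adjusted p = 0.0182, rescaled 0.80 with 0.121; -0.31 from week 1), and Abl1 (1.08, adjusted p = 0.159) did not pass. Ngp was higher by 5.54 ± 0.79 (adjusted p = 3.29e-06, 7 of 7 mice), but not after rescaling (4.95, adjusted p = 0.0671). The actin regulator Dstn (4.22 ± 0.64), tropomyosin Tpm2 (4.20), Clca3a1 (4.12) and Gp1bb (4.09) were higher and passed after rescaling too, yet from week 1 they stood at -0.015, -0.10, -0.41 and -0.30. Platelet genes were higher in 20 of 20 (median 2.91, adjusted p = 0.0149 with an estimated correlation; 4 rescaled, 0.411), and secondary granule genes in 14 of 17 (16 adjusted over the list alone; adjusted p = 0.0496 with an estimated correlation; 0 rescaled, 0.471). Stem and progenitor genes were higher in 6 of 7 (adjusted p = 0.0298 with an estimated correlation; 2 rescaled), with Cd34 at 3.44, which flipped to -0.54 from week 1.

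Haemoglobin genes were lower in 5 of 6 (median -1.73; adjusted p = 2.82e-05 with an estimated correlation), with Hbb-bs at -1.84 ± 0.54 (adjusted p = 0.0147). The haemoglobin calls were lost after rescaling and without control mouse 489 (adjusted p from 0.413 to 0.579) or 490 (0.0748 to 0.161), and from week 1 with rescaling Hbb-bs stood at 0.62. The erythroid list (2 higher, 4 lower of 26, median -0.87) also passed with an estimated correlation (adjusted p = 0.00113). The cell cycle list was lower relative to other genes although its median was 0.38 (adjusted p = 0.00159 with an estimated correlation; rescaled median -0.42, 0.444), with Nusap1 at -1.55 (adjusted p = 0.0688) and Ube2c at -1.48 (adjusted p = 0.0904). For TKI week 10 against week 0 minus control, 1664 genes passed, 1658 higher, with an all-gene median of 0.999, and 375 after rescaling (78.7% higher, 279 shared). From week 1 in place of week 0 limma called 0 (1049 at unadjusted p under 0.05). The count was 107 without control mouse 489, 461 without 490, 8798 without 488 and 2721 without CML mouse 541. In batch 2022_A (4 against 1 mice) the secondary granule median was 0.859 and the platelet median 2.13, each minus the all-gene median. The all-gene median itself was -0.178, opposite in sign to that of all mice. With a batch term 268 genes passed.

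Both interventions were set side by side as the change from week 6 to week 8 in 4 TOTO minus 7 TKI mice. The transgene was lower in TOTO mice, at -1.27 ± 0.51 (adjusted p = 0.0248, rescaled -2.05). This call was lost without TOTO mouse 482 (adjusted p = 0.0556) or 483 (0.161). Bcr was at 0.81 (adjusted p = 0.0602), which flipped to -0.91 after rescaling, and Abl1 at 1.77 (adjusted p = 0.000271, rescaled 0.19 with 0.0785). B cell genes were higher in 19 of 19 on both scales (median 3.11, rescaled 1.28; adjusted p = 0.166 with an estimated correlation), with the surrogate light chain gene Vpreb3 at 4.01, the transcription factor Spib at 3.97 and Niban3 at 4.38 ± 0.37. Erythroid genes were lower in 12 of 26 (10 adjusted over the list alone; adjusted p = 0.0002 with an estimated correlation) and in 25 after rescaling (0.732). Haemoglobin genes were lower in 5 of 6 (adjusted p = 0.00609 with an estimated correlation), with Hbb-bs at -1.18 (3 of 4 mice). Platelet genes were lower in 3 of 20 (adjusted p = 0.0847 with an estimated correlation) and in 20 after rescaling, with Gp1bb at -2.10 and Selp at -1.66. Secondary granule genes went both ways as deposited (3 higher, 3 lower of 17), and 12 were lower after rescaling (median -1.796; adjusted p = 0.593 with an estimated correlation). Ribosomal protein genes flipped from 57 of 59 higher to 37 lower after rescaling, and the T cell median from 1.29 to -0.17. In total 8623 genes passed, 98.6% higher, with an all-gene median of 1.391. After rescaling 5438 passed, 44.9% higher, and 1270 had the opposite sign. Within batch 2022_A (4 against 4 mice) the all-gene median was 1.579. The rescaled secondary granule median minus the all-gene median was -1.742 there.

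Between 10 female and 7 male Tet-off mice limma called 0 genes for a difference in the induction change (24 at unadjusted p under 0.05, and 236 after rescaling, again with 0 called). The transgene differed by 0.27 ± 0.58 (adjusted p = 1). T cell genes had a median of -0.31 in females minus males (0 of 20), and after rescaling the list passed with an estimated correlation (median -0.39, adjusted p = 0.0259; 0.931 as deposited), with 0 of 20 genes lower over all genes and 5 adjusted over the list alone.

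Across the 12 comparisons, 19, 18, 16, 15, 14, 13, 15, 16, 16, 18, 14 and 7 of 26 lists passed with the preset correlation in the order described, and 1, 1, 4, 0, 1, 1, 2, 1, 2, 6, 2 and 0 with an estimated correlation. As deposited, the secondary granule list held with an estimated correlation in 8 comparisons: both induction comparisons, the CML end state, TKI minus CML, after nilotinib, both TOTO week 12 comparisons and TKI week 10 against week 0. After rescaling it held in 2 of them, the CML end state and TOTO week 12 against week 6. Median, mean and test of a list differed in sign in 3 to 15 lists per comparison as deposited, and in at most 3 after rescaling.

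**Figure D5:**
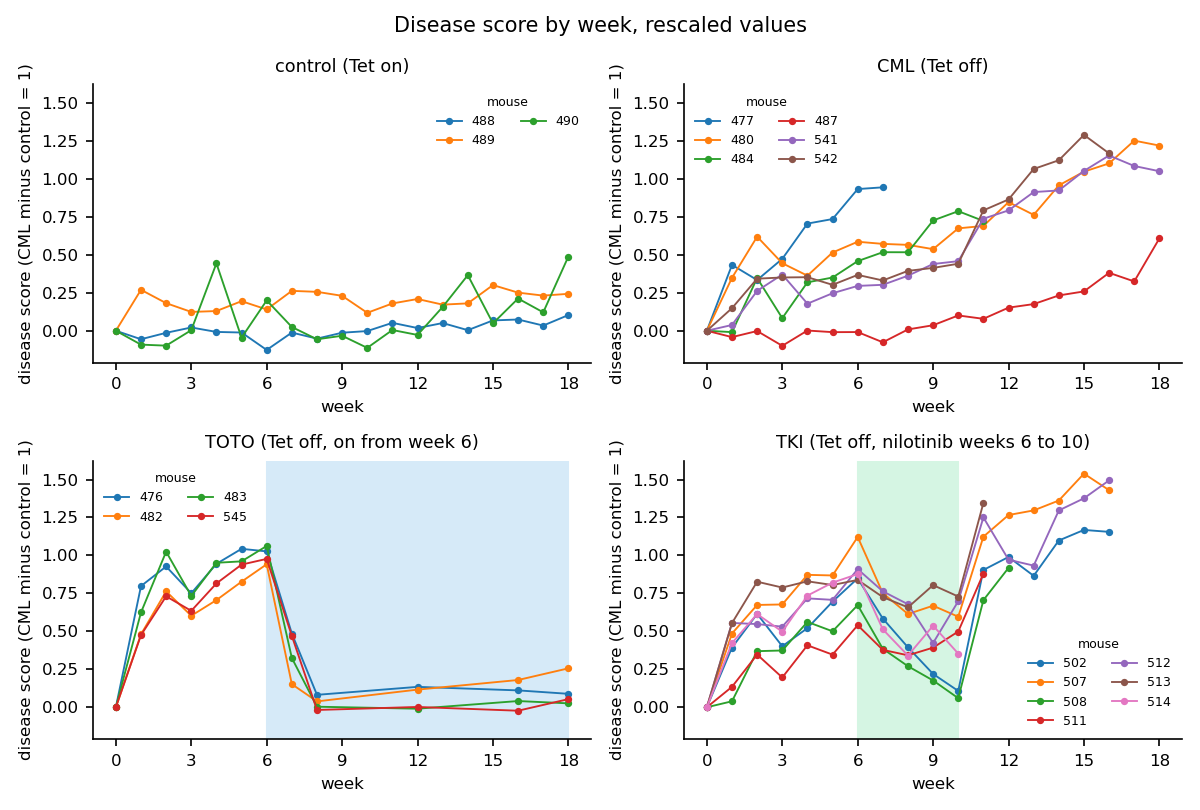
Rescaled disease score of each mouse by week (0 at week 0 of the same mouse, 1 unit being the CML change minus the control change at the end), 1 panel per cohort and 1 line per mouse. TOTO mice were at 1.00 at week 6 and 0.0265 at week 8, and TKI mice at 0.830 at week 6 and 0.435 at week 10. The mouse labelled CML 487 was at -0.0086 at week 6 and 0.608 at week 18.

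The disease score placed each library on an axis of the CML change minus the control change, the mouse labelled CML 487 contributing to the axis. As deposited, 17 Tet-off mice scored 0.547 ± 0.717 (SD) at week 6 and 3 control mice 0.293 ± 0.835, a difference of 0.253 (exact permutation p = 0.603, adjusted over 4 tests 0.603). After rescaling the scores were 0.732 ± 0.314 and 0.0713 ± 0.174 (difference 0.661, exact p = 0.00351). The Tet-off cohorts differed at week 6. CML mice alone stood at -0.060 ± 0.811 (n = 6) as deposited and 0.439 ± 0.314 rescaled, below the TOTO and TKI means on both scales. Changes counted from week 6 thus began at unequal levels, which the tests between cohorts did not take into account. Without control mouse 488 the difference as deposited was -0.185. From week 6 to 10 the score changed by -0.389 ± 0.269 (n = 7) in TKI mice under nilotinib and by 0.214 ± 0.447 (n = 5) in CML mice, a difference of -0.603 (exact p = 0.00758, adjusted 0.0303; rescaled -0.548, exact p = 0.00505). Without CML mouse 484 it was -0.336 (exact p = 0.0697, adjusted 0.171). The adjusted p also missed the threshold without CML mouse 487 (0.1455), 480 (0.0606) or 477 (0.0571) and without control mouse 488 (0.1515) or 489 (0.0884). TOTO mice differed from CML mice by -0.718 over weeks 6 to 12 (exact p = 0.0571; rescaled -1.295, exact p = 0.0286, the smallest these mice allow). As deposited that difference was 0.0335 without CML 487 and 0.101 without control mouse 488. At week 18 TOTO mice differed from control mice by -0.702 (exact p = 0.0571; rescaled -0.173, exact p = 0.171), and by 0.506 without control mouse 489.

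Rescaled scores of TOTO mice were 1.00 ± 0.0531 (SD, n = 4) at week 6, 0.358 ± 0.155 at week 7, 0.0265 ± 0.0436 at week 8 and 0.106 ± 0.103 at week 18. TKI mice scored 0.830 ± 0.184 at week 6, 0.435 ± 0.271 at week 10, 1.04 ± 0.245 (n = 6) at week 11 and 1.36 ± 0.180 (n = 3) at week 16. CML mice were at 0.960 ± 0.316 (n = 3) and control mice at 0.279 ± 0.195 (n = 3) at week 18, an order that was the opposite as deposited (0.315 ± 0.869 and 0.536 ± 0.717). As deposited, TOTO mice scored 0.548 ± 0.447 at week 6, -0.0965 ± 0.184 at week 8 and -0.167 ± 0.196 at week 18, and TKI mice 1.06 ± 0.199 at week 6, 0.677 ± 0.210 at week 10 and 1.40 ± 0.182 at week 11. Within batches the week 6 difference was -0.442 in 2021_E (2 against 2) and 0.988 in 2022_A (10 against 1), or 0.271 and 1.02 rescaled. The TKI against CML difference was -1.51 in 2022_A (4 against 1) and -0.265 in 2022_B (3 against 2). Without CML 487 the latter was 0.0235 (3 against 1; rescaled -0.218), so that its direction as deposited rests on that mouse. No batch held TOTO and CML mice with both weeks. The week 18 difference between TOTO and control mice in 2022_A (4 against 1) was -0.131 as deposited and 0.00259 rescaled. Whether the week 6 score went with the last sampled week was tested over 13 CML and TKI mice, with r = -0.249 (permutation p = 0.408) and rho = -0.378 (permutation p = 0.204), and r = -0.418 without the 2 farthest mice. Within 6 CML mice r was -0.283 (exact p = 0.617, rescaled -0.748 with 0.0833) and within 7 TKI mice 0.672 (exact p = 0.124, rescaled 0.580 with 0.214), so the pooled value joins cohorts with opposite signs. Without the 2 farthest mice r was -0.977 in CML and -0.282 in TKI mice. Within batch 2022_A (6 mice) r was 0.381 (exact p = 0.45), and the other batches held too few mice.

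Genes called for induction in mice outside the cohort examined were followed back. In TKI mice 307 of 7483 such genes (4.1%) were called the opposite way from week 6 to week 10, or 2398 of 7207 (33.3%) after rescaling. The median share of the other mice's induction change seen in TKI mice was 84.6% at week 6 and 48.1% at week 10 after rescaling, but -39.8% and -46.1% as deposited. In TOTO mice 461 of 619 (74.5%) were called the opposite way by week 12, or 5270 of 6640 (79.4%) after rescaling. Their median share was 153% at week 6, 23.5% at week 12 and 32.4% at week 18 after rescaling, and 57.9%, -30.7% and -28.6% as deposited. Counted from week 1 in place of week 0 and rescaled, the cohorts were close in genes called the opposite way. These were 2374 of 4341 (54.7%) in TKI and 2720 of 5135 (53%) in TOTO mice. A further 694 genes in TOTO and 11 in TKI mice were called the same way. The induction gene sets differ between the cohorts, so neither the counts nor the shares are a test between them. Of the variance over all libraries, 56.5% lay on the first principal component, which followed the median expression of a library (absolute r = 0.997 across libraries), and 17.8% on the next, which followed the rescaled score (absolute r = 0.895).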

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

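All tests of explanations and of other splits in this part were chosen after the results were seen, whereas the comparisons they refer to were planned. Of 133 groups of 4 to 10 mice, 9 held a mouse far from the others, and chance alone gives about 1 in 20. Haemoglobin made up 55.12% of TPM at week 0 in TOTO mouse 545, against 9.63 to 13.83% in the other 3. The rescaled transgene change from week 6 to 8 was -2.352 in TKI mouse 507, against -1.015 to -0.456. From week 8 to 10 Ngp changed by 2.11 in TKI mouse 513 (others -0.357 to 0.649) and Camp by 1.813 (others -0.502 to 0.425). The mouse labelled CML 487 stood apart in the rescaled mature neutrophil list from week 6 to 8 (-0.5718, others -0.0281 to 0.110) and in the immediate early list from week 6 to 12 (0.9152, others -0.326 to -0.128). TOTO mouse 482 had a B cell list change of 1.105 from week 6 to 12 (others 1.499 to 1.523). From week 0 to 18 TOTO mouse 545 had a rescaled transgene change of -0.2928 (others 0) and an Ngp change of -0.0002852 (others -0.743 to -0.649).

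Differences between cohorts in 5 tested changes were flagged, and not all of them are settled. In TKI minus CML mice from week 6 to 10, 375 genes passed, in TOTO minus CML mice from week 6 to 12, 6219, and in TOTO minus TKI mice from week 6 to 8, 8623. The disease score change of TKI against CML mice differed by -0.6026, and their rescaled transgene change from week 6 to 8 by -1.889. For TOTO minus CML as deposited, 3 of 35 splits of the mice gave as many genes, so chance could not be excluded. The adjusted p of the score difference missed the threshold without any of several single mice.

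The first pattern is the lower transgene level at week 8 of nilotinib. Week 8 was picked as the lowest week of treatment, and its p values are not adjusted over weeks. A lower share of all genes in the week 8 libraries is argued against by the rescaled change of -0.9008 (SD 0.667, 7 of 7 mice lower, exact sign-flip p = 0.0156). A difference between batches is argued against because 7 of 7 mice of both batches were lower. Fewer neutrophils carrying the transgene stays open: from week 8 to 10 the transgene rose over the secondary granule list by 0.7947 (SD 0.795, 5 of 7 mice, exact p = 0.0625). An effect of nilotinib itself, which the design names, also stays open and was not tested apart from cell composition.

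The mouse labelled CML 487, with the transgene at 0 TPM in 16 of 19 libraries, is the next pattern. A swap with a control mouse is argued against, since the highest mean human ABL1 level of a control mouse from week 6 was 0.08979 TPM, while the lowest of the other 16 Tet-off mice was 2.66 TPM. A wrong label, or a mouse that never switched the transgene on, stays open. The mean human ABL1 level of CML 487 from week 6 was 0.04249 TPM, below that of the highest control mouse. The rescaled disease score of CML 487 at week 18 was 0.6081, above the control mice (0.103 to 0.489) and below the other CML mice (1.05 to 1.22).

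The last pattern is that most genes had a lower mean at week 6 than at week 0 in Tet-off mice (all-gene median -0.339), although the median was below 0 in only 7 of 17 mice and above it in 10 (SD 1.23). The cohorts moved opposite ways. The mean number of genes at 1 TPM or more fell from week 0 to 6 in CML (11360 to 9384) and TOTO mice (12520 to 8968). In TKI mice it rose (8374 to 10080), so the pooled median is not a pattern of every cohort. A few abundant genes taking most of the TPM are argued against as the whole cause, since with the 10 most abundant genes left out the median was -0.2409 (SD 0.307, 14 of 17 mice lower). Week 0 libraries that differ from the later ones are consistent with the median of 0.153 counted from week 1 (SD 0.612, 11 of 17 mice higher). The 10 most abundant genes held 74.4% of TPM at week 0, 81.2% at week 1 and 78.4% at week 6. No biological explanation was tested.

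Other splits of the mice or of their signs were counted for each comparison, the real one included. For the induction change in Tet-off mice, 1 of 100 splits gave as many genes (real 2153, highest other 801), for TKI week 10 against week 6, 1 of 64 (839 and 476), and for the TKI last sample against week 10, 1 of 32 (2964 and 2225). For TKI week 10 against week 6 minus CML it was 2 of 100 (375 and 561), for TKI week 10 against week 0 minus control 2 of 100 (1664 and 8964), and for TOTO minus TKI change from week 6 to week 8, 1 of 100 (8623 and 8340). For these 6 the share was under 0.05 among splits that ignore batch, unadjusted over the comparisons. For the TKI last sample 1 of 32 is the smallest share possible. For TKI week 10 against week 0 another split called several times the real count. The splits do not exclude batch, which ran with cohort: all TOTO mice were in 2022_A, no TKI mouse was in 2021_E, and with a batch term the count was 736 for the induction change in Tet-off mice, 842 for TKI week 10 against week 6 minus CML and 268 for TKI week 10 against week 0 minus control. For TOTO minus TKI, batch 2022_A alone held 4 mice of each cohort, with an all-gene median of 1.579 against 1.391 over all mice. Chance could not be excluded for the induction change Tet-off minus control (9 of 100, real 2, highest other 9659), the CML last sample change minus control (8 of 84, 19 and 8841), TOTO week 12 against week 6 minus CML (3 of 35, 6219 and 8051) or TOTO week 18 against week 0 minus control (3 of 35, 2 and 2). For the sex difference in induction change the real count is 0, so that 100 of 100 splits reach it by construction (highest other 9073) and nothing follows. After rescaling, 2 of 100 (real 1900, highest other 2354), 1 of 84 (957 and 880) and 1 of 35 (6795 and 6) splits gave as many in the first 3 comparisons for which chance could not be excluded. The share was thus under 0.05 there, again unadjusted and without regard to batch. The rescaled share was also under 0.05 for the induction change in Tet-off mice (1 of 100, 7701 and 5746), TKI week 10 against week 6 (1 of 64, 3640 and 2698), TKI minus CML (3 of 100, 2169 and 2849), the TKI last sample (1 of 32, 5550 and 0), TKI week 10 against week 0 (2 of 100, 375 and 544) and TOTO minus TKI (1 of 100, 5438 and 3299). For TOTO week 18 and the sexes the rescaled count is 0, and the splits decide nothing (highest other 1 and 529). For TOTO week 12 against week 6 the 8 splits are too few for a share under 0.05 (2 of 8, 5268 and 6790; rescaled 1 of 8, 6479 and 2). Splits that call several times the real count point to a structure of the samples, and such splits were seen as deposited for Tet-off minus control, the CML end state, TKI week 10 against week 0 and the sexes.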

How the results depend on the processing

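TPM are shares, so a shift of most genes together decides many calls, and depth, which TPM does not keep, could not be used as a limit. The alternatives that use week 1 in place of week 0, or leave out the mouse labelled CML 487 or TKI mice 507 and 512, and those that leave a mouse out of the score, were chosen after seeing the data. DESeq2 was not run because the values are not counts. Of the settings tried on 236 named gene results, 3614 kept their side of the threshold, 227 lost the call, 56 gained one and 27 reversed. A change of sign where neither value passed was counted as kept, so direction was not always kept in the 3614. Reversed means a change of sign with at least 1 of the values past the threshold. For counts and tests, with score tests judged by their unadjusted exact p, 193 were the same, 95 moved, 12 gained a call, 1 lost it and 5 reversed. The cause of a change was not tested unless given. Where limma called 0 genes, the count at unadjusted p under 0.05 is given beside it.

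The induction change in Tet-off mice (2153 genes) gave 4455 with no filter on low values, 7701 with median-ratio size factors, 6613 with haemoglobin and erythroid genes left out, 736 with a batch term on the change, 1256 with week 5 in place of week 6, and 6452 from week 1 with median-ratio size factors. From week 1, 2204 passed with 87.7% higher. Leaving out 1 control or TOTO mouse gave 1293 to 2068. Counted from week 1, Gp1bb was at -0.24 (rescaled -0.45), Selp at -0.83 (-1.03) and H2-DMb1 at 0.018. The value of Pkm in induction change in Tet-off mice was -0.0019 (rescaled -0.22). Bcr was at 0.31 after rescaling.

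The induction change Tet-off minus control (2 genes) gave 0 with no filter (360 unadjusted), 1900 rescaled, 1 without haemoglobin and erythroid genes, 0 with no replicate block for the paired libraries (409), 0 with a batch term (77), 4 from week 5, 0 from week 1 (184) and 0 from week 1 rescaled (1851). Leaving out 1 control or TOTO mouse gave 0 to 3.

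The CML last sample change minus control (19 genes) gave 5 with pseudocount 0.1, 12 with no filter, 957 rescaled, 31 without haemoglobin and erythroid genes, 4 with no replicate block, 80 with a batch term, 56 without CML 487, 9 from week 1 and 119 from week 1 rescaled. Leaving out 1 control or TOTO mouse gave 17 to 43.

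TKI week 10 against week 6 (839 genes) gave 3640 rescaled, 2387 (58.9% higher) without haemoglobin and erythroid genes, 0 with no replicate block (1446 unadjusted) and 354 (54.8% higher) with week 9 in place of week 10. Leaving out 1 CML or control mouse, whose spread enters the fit, gave 740 to 1197, and no TKI mouse was left out. TKI week 10 against week 6 minus CML (375) gave 2169 rescaled, 1054 (56.3% higher) without haemoglobin and erythroid genes, 0 with no replicate block (989), 842 with a batch term and 36 with week 9, and 113 to 525 with 1 CML or control mouse left out. TKI last sample against week 10 (2964) gave 5550 rescaled, 1244 without TKI mice 507 and 512 (fewer mice), and 2676 to 3094 with 1 control mouse left out. With a batch term 2545 passed, 62.9% higher.

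TOTO week 12 against week 6 (5268 genes) gave 103 with a batch term, and 2411 to 7217 with 1 mouse left out. Bcr was at -0.58 rescaled. TOTO week 12 against week 6 minus CML (6219) gave 59 with a batch term and 4853 to 7631 with 1 mouse left out, and Bcr was at -1.17 rescaled. TOTO week 18 against week 0 minus control (2) gave 1 with pseudocount 0.1, 0 with no filter (100 unadjusted), 0 rescaled (108), 0 without haemoglobin and erythroid genes (32), 0 with no replicate block (10), 0 with week 16 in place of week 18 (35), 7 from week 1 and 15 from week 1 rescaled. Leaving out 1 mouse gave 2 to 7.

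TKI week 10 against week 0 minus control (1664 genes) gave 375 rescaled, 524 without haemoglobin and erythroid genes, 268 with a batch term, 0 from week 1 (1049 unadjusted) and 0 from week 1 rescaled (1224). Leaving out 1 CML or control mouse gave 107 to 8798. From week 1 Dstn was at -0.015, Tpm2 at -0.10, Clca3a1 at -0.41, Gp1bb at -0.30, Selp at -0.98 (rescaled -0.22), Cd34 at -0.54 (-0.63), Muc13 at -0.29, Gata1 at -0.091 and Bcr at -0.31. From week 1 rescaled, Hba-a1 was at 0.71, Hba-a2 at 0.68, Hbq1a at 0.58, Hbb-bt at 0.50 and Hbb-bs at 0.62. TOTO minus TKI change from week 6 to week 8 (8623) gave 5438 rescaled and 7722 to 9263 with 1 CML, control or TOTO mouse left out, with Bcr at -0.91 rescaled. The sex difference in induction change stayed at 0 in every alternative run (13 to 236 unadjusted).

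For the disease score, Tet-off against control at week 6 (0.253) gave 0.661 rescaled, 0.561 without haemoglobin and erythroid genes and 0.632 rescaled without CML 487 (adjusted p 0.0101, 0.0398 and 0.00413), and -0.185 to 0.416 with 1 mouse left out. The disease score, TKI against CML change from week 6 to 10 (-0.603) gave -0.650 to -0.336 with 1 mouse left out, and its adjusted p missed the threshold without CML 477, 480, 484 or 487 or control 488 or 489. The disease score, TOTO against CML change from week 6 to 12 (-0.718) gave -0.883 with the top 500 axis genes, -1.295 rescaled, -1.505 without haemoglobin and erythroid genes, -0.834 with pseudocount 0.1 and -1.079 rescaled without CML 487. Each of these 5 had an unadjusted exact p of 0.0286. Adjusted over 4 tests, the top 500 axis genes and pseudocount 0.1 missed the threshold (0.0571 each), and the other 3 passed (0.0381, 0.0398 and 0.0381). It was 0.0335 without CML 487, and -1.663 to 0.101 with 1 mouse left out. TOTO against control at week 18 gave -1.287 to 0.506.

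In the reversal of induction genes, genes called the opposite way in TKI mice numbered 307, and 2398 rescaled, 1188 without haemoglobin and erythroid genes and 2374 from week 1 rescaled. In TOTO mice they numbered 461, and 5270, 3674 and 2720. As shares of the induction genes these were 4.1, 33.3, 14.7 and 54.7% in TKI mice and 74.5, 79.4, 88.3 and 53% in TOTO mice. The median remaining share was -46.1% in TKI mice at week 10, and 48.1, -4.23 and 12.7% in the same order. In TOTO mice at week 12 it was -30.7%, and 23.5, 71.4 and 6.38%. In the gene lists, camera with an estimated correlation left 1 list for the induction change in Tet-off mice, 1 for Tet-off minus control, 4 for the CML end state, 0 for TKI week 10 against week 6, 1 for TKI minus CML, 1 after nilotinib, 2 for TOTO week 12, 1 for TOTO minus CML, 2 for TOTO week 18, 6 for TKI week 10 against week 0, 2 for TOTO minus TKI and 0 between the sexes. The first principal component held 34.9% of the variance rescaled, against 56.5%.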

Other observations

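In control mice the haemoglobin share of TPM was 38.1% at week 0, 59.3 ± 13.0% (SD, n = 3) at week 6 and 53.3% at week 18. In CML mice it was 33.3 ± 25.9% at week 0 (n = 6), 47.1 ± 11.0% at week 6 and 25.5 ± 24.6% at week 18 (n = 3). TOTO mice went from 44.5% at week 6 to 52.3 ± 4.70% at week 18 (n = 4).

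The test in this paragraph was chosen after the result was seen. That mice with more transgene at week 6 have a higher rescaled disease score was tested as a hypothesis over 17 Tet-off mice. The score includes the human transcripts among its genes, so the relation is partly built in, and no score without them was run. Pearson's r was 0.7817 (permutation p = 0.00026) and rho 0.65 (permutation p = 0.00576), and r was 0.629 without the 2 farthest mice. Without the mouse labelled CML 487 r was 0.680 (permutation p = 0.00448) and rho 0.579 (permutation p = 0.0213). Within batch 2022_A (10 mice) r was 0.608 (permutation p = 0.065) and rho 0.467 (permutation p = 0.179), and r was -0.213 without the 2 farthest mice, so that inside this batch the relation rests on those mice. The other batches held 2 and 5 Tet-off mice, too few to test. Cohort and batch overlap, so a difference between batches stays open beside the hypothesis.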
